A study of Mus musculus with 4 samples.

How the data were processed

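Chromatin was prepared from embryoid bodies of 20 dishes of 10 cm at day 6, fixed for 15 min in 1% formaldehyde, and 30 µg of it entered each immunoprecipitation, per the labels' protocols. The stem cells were of passages 8 to 12, had been kept with inhibitors of MEK and GSK3, and differentiated in medium with 20% serum, per the labels. The 4 libraries are Trim33, CTCF, H3K27ac and input DNA, 1 of each. In the authors' deposited table the Trim33 and input libraries carry a different project code from the CTCF and H3K27ac libraries, so the antibody and this code cannot be told apart.

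The submitters' processing notes name BWA 0.7.12, MACS, MACS2 and SICER 1.1 and the builds mm10 and hg19, without saying which tool made which file. The authors' deposited summary names MACS 2.1.0 and tags of 75 bp, and gives an effective genome size of 1.87e+09 and 2 p-value cut-offs, 1e-05 and 1e-07. The lowest −log10 p in the deposited lists was 5.06 for Trim33 and 7.03 for both other lists, so the Trim33 list was made at the looser cut-off. The peak lists hold, per peak, the authors' fold enrichment (a ratio over background), −log10 p, −log10 q and the summit. They were called separately for each antibody against the input, which was used by the authors with 13643929 tags for Trim33 and 25729171 tags for the others. The authors removed 83, 210 and 407 peaks in blacklisted regions, leaving 4426, 52446 and 30047. The authors' deposited summary also gives counts of reads and of peaks per library, per chromosome and per merged region, and the share of peaks at annotated features as a fraction. Reads numbered 29719237 for Trim33, 43900248 for CTCF, 38080890 for H3K27ac and 35873121 for the input. With 0.72% of reads inside peaks, the Trim33 library has the least power, and sites missing from its list may fall below detection at this depth. Fold and q were used to rank, filter and compare peaks within a list. In addition, Trim33 fold less 1 was divided by CTCF fold less 1 at shared peaks (the ratio of enrichment), and tags were recovered from fold and p, for the closing tests only. Intervals cover counting error only.

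Everything else was computed from the lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks overlapped if they shared at least 1 bp. Each overlap was compared with 1000 random placements (seed 20) of the first list on its own chromosomes, between the outermost peaks of the 3 lists. Placements did not avoid assembly gaps, unmappable or blacklisted sequence, where no peak can be listed, so the excess over placement may be too high. Tables of 2 by 2 were tested with Fisher's exact test (two-sided), strata with the Mantel-Haenszel odds ratio, and heights with a two-sided permutation test of mean log2 fold (100000 resamples, smallest p 1e-05). P-values were adjusted by Benjamini and Hochberg over 5 height tests or, per antibody, over 15 gene lists. Shares have 95% Wilson intervals. Gene positions came from the RefSeq table of GRCm38.p6, the assembly of mm10, with 49943 genes on the chromosomes used. That table has no strand and no exons, so peaks were assigned to the nearer of both gene ends rather than to transcript starts, and exons and introns were not told apart. All 894 list entries matched a gene, Nespas by the older name of Gnasas1. That match was added after the first results had been seen, and no list crossed the threshold with it.

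Genes were named by a rule fixed before the data were examined. It takes the nearest protein-coding gene to the 15 highest Trim33 peaks, to the 10 highest with both CTCF and H3K27ac, to the 5 highest with CTCF alone and the 5 highest with neither, and to the 5 highest CTCF and H3K27ac peaks. It adds up to 6 members per list with Trim33 within 1 kb of an end, Trim33 and Ctcf, the H19 and Igf2 region and the clustered protocadherins. Gse1, Grb10, Mest and the members named for the ribosomal list and for H3K27ac were chosen after their values were seen, as were the imprinted members beyond the first 6. Placement was tested on simulated data made from the 4426 Trim33 peaks, where 1000 planted overlaps with CTCF were all recovered and 2 of 40 runs without an effect passed 0.05. For the odds ratio within the 30047 H3K27ac peaks, a simulated value of 3 came back as 2.98, and the interval missed it in 4 of 100 runs. For the height of Trim33 peaks with and without CTCF, 1 of 40 runs without an effect passed 0.05. Marks in the simulations of odds ratio and height were drawn without regard to position. They therefore do not test the effect of neighbouring peaks that are not independent.

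Alternatives fixed before the data were examined were a −log10 q of at least 10, the higher part of each list above its median fold, other definitions of overlap, no sex chromosomes, placement within 20 to 200 kb, H3K27ac peaks within 1 kb joined, strata, a 5 kb window, the nearest gene within 50 kb, protein-coding genes only, and backgrounds of acetylated genes. Added after seeing the data were a −log10 p of at least 7 for Trim33, neighbouring genes as 1 unit (ends within 2 kb, for all 3 antibodies), whole genes in strata of length, and a ribosomal list without other genes of the same prefix. Sequence motifs and repeats at summits were not analysed here.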

Results

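Embryoid bodies are aggregates in which mouse embryonic stem cells differentiate into cells of several germ layers, and those studied here were harvested at day 6 of culture. Chromatin immunoprecipitation followed by sequencing was carried out with antibodies against Trim33, CTCF and histone H3 acetylated at lysine 27 (H3K27ac). Trim33 is a chromatin-binding protein of the TRIM family that takes part in Nodal and TGF-beta signalling. CTCF is the zinc finger protein that binds insulators and chromatin loop anchors, and H3K27ac marks active promoters and enhancers. There was 1 library for each of the 3 antibodies and 1 library of input DNA, so no value below has a replicate check, and each test describes these libraries rather than the condition. The stem cells came from blastocysts with a conditional Trim33 allele and an inducible Cre, and no comparison with cells lacking Trim33 was analysed here. According to the authors' deposited summary, 13643929 tags were used for Trim33, 33090822 for CTCF, 29995044 for H3K27ac and 25729171 for the input. Duplicates made up 40.9% of the uniquely aligned reads in the Trim33 library, against 12.2% for CTCF, 6.36% for H3K27ac and 7.09% for the input. The share of reads inside peaks was 0.72% for Trim33, 26.46% for CTCF and 13.02% for H3K27ac, as the same summary gives it.

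The first question was where in the genome each antibody gave peaks. CTCF had 52446 peaks, H3K27ac 30047 and Trim33 4426. Trim33 peaks were short, with a median width of 264 bp and a median fold of 5.67 over background, and the highest reached 20.4. The highest CTCF peak had a fold of 60.6 and lay 38 bp from an end of Dnajc11, which encodes a mitochondrial DnaJ protein. The highest H3K27ac peak had a fold of 45.3 and lay inside Rbm39, a splicing factor gene. The next highest acetylated sites were in Hnrnpu, which encodes a nuclear RNA-binding protein, with a fold of 44.6, in Ccdc58 with 42.5, in Rpl19, a ribosomal protein gene, with 41.0, and in Pkm, the pyruvate kinase gene of glycolysis, with 40.6. After Dnajc11, the highest CTCF peaks lay near Med4, a Mediator subunit gene, with a fold of 58.3, near Glrx3, a glutaredoxin gene, with 57.7, near Dhx8, an RNA helicase gene of the spliceosome, with 57.6, and near Csrp1 with 57.1. These folds are the authors' values and rank peaks within a list, not between lists.

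Trim33 and H3K27ac peaks were concentrated at gene ends, and CTCF peaks less so. A summit lay within 1 kb of either end of an annotated gene for 37.4% of Trim33 peaks (95% Wilson interval 36.0 to 38.8), 18.0% of CTCF peaks (17.7 to 18.4) and 39.7% of H3K27ac peaks (39.2 to 40.3). Peaks placed at random gave 6.46%, 6.54% and 6.58% in the same order. Of the other Trim33 peaks, 31.9% of the list lay inside genes and 30.7% between them, while 49.1% of CTCF peaks and 43.2% of H3K27ac peaks lay inside genes away from their ends. The authors' deposited table puts 1112 Trim33 peaks (25.1%), 3754 CTCF peaks (7.16%) and 8822 H3K27ac peaks (29.4%) within 500 bp of a transcript start. By the authors' deposited table, 35.5% of Trim33 peaks, 10.4% of CTCF peaks and 34.9% of H3K27ac peaks were at CpG islands. Because the gene table used here has no strand, an end can be a start or a finish of transcription.

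The second question was whether Trim33 occupied the sites bound by CTCF. Of the 4426 Trim33 peaks, 1979 overlapped a CTCF peak, a share of 44.7% (95% Wilson interval 43.3 to 46.2). Random placement on the same chromosomes gave 90.4 ± 9.51 overlaps (SD over 1000 placements), so the observed number was 21.9 times higher (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The strongest shared site without H3K27ac lay between genes on chromosome 7 from 137477978 to 137478697 (build mm10), 8.79 kb from Glrx3 (gene ID 30926), with a Trim33 fold of 20.1 over a CTCF peak that ranks among the 5 highest of its list. Trim33 peaks with CTCF and without H3K27ac also stood near Kiss1r, the receptor gene for kisspeptin, with a fold of 16.2, inside Gnat1, which encodes rod transducin, with 16.0, near Eif4b, a translation initiation factor gene, with 15.7, and 2.73 kb from Foxc2, a forkhead gene of mesoderm, with 14.1. Seen from the other side, 1926 of the 52446 CTCF peaks (3.67%) carried a Trim33 peak.

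CTCF peaks that carried Trim33 were among the higher ones. Their median fold was 25.6, against 9.22 for CTCF peaks without Trim33, and the mean log2 fold differed by 1.15 ± 0.02 (SE; two-sided permutation p adjusted by Benjamini-Hochberg over 5 tests = 1.67e-05, the smallest reached). Trim33 was present at 0.534% of the lowest decile of CTCF peaks, at 6.20% of the ninth and at 20.7% of the highest. In the top 1% of CTCF peaks, 217 of 525 carried Trim33, or 41.3% (37.2 to 45.6). Trim33 peaks themselves were slightly higher with CTCF than without, with median folds of 5.81 and 5.63 (log2 difference 0.04 ± 0.01, SE; adjusted permutation p = 0.000288). That small difference was not past the threshold away from gene ends (adjusted permutation p = 0.065). When each Trim33 peak was moved by 20 to 200 kb instead, 171 ± 12.4 overlaps with CTCF were placed and the excess was 11.5 times.

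**Figure D1:**
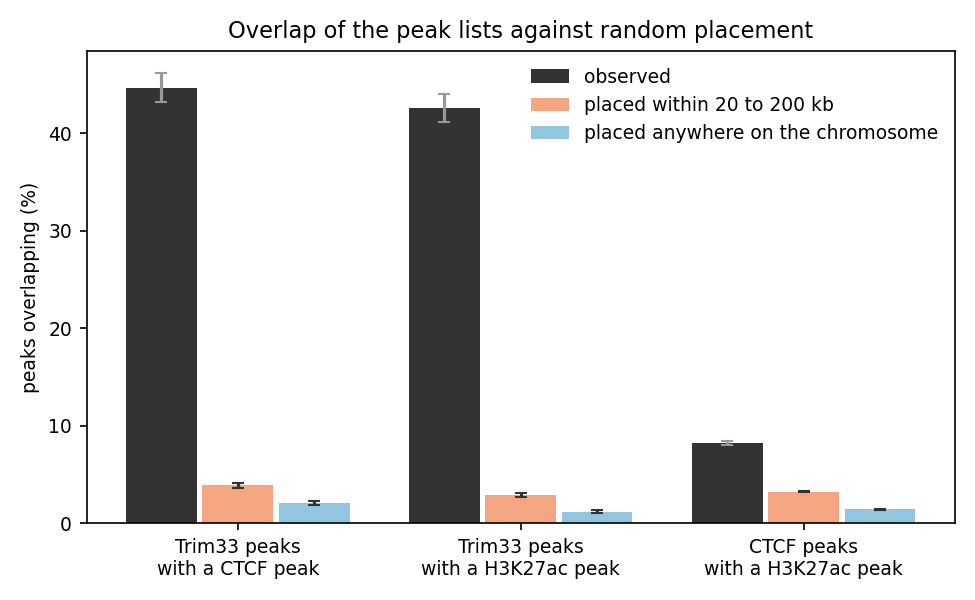
Bars give the share of peaks (%) of the first list that overlap a peak of the second, as observed (with 95% Wilson intervals) and as the mean of 1000 random placements (with SD) near the peak or anywhere on its chromosome. The observed shares are 44.7%, 42.6% and 8.23%, each above both placements.

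The third question was how Trim33 peaks related to acetylated chromatin. Of the Trim33 peaks, 1885 overlapped an H3K27ac peak, a share of 42.6% (41.1 to 44.1), where random placement gave 52.9 ± 7.12, so the observed number was 35.7 times higher (one-sided permutation p = 0.001, the smallest possible). The highest of these was on chromosome 17 from 45805396 to 45806096, with a fold of 20.4, about 71.8 kb from 1600014C23Rik, and it overlapped CTCF too. Ccn2 (gene ID 14219), which encodes a matricellular protein induced by TGF-beta, had a Trim33 peak of fold 17.8 on chromosome 10 from 24595058 to 24595994, with its summit inside the gene and 53 bp from its end, over an H3K27ac peak of fold 14.4. Others of the highest 15 Trim33 peaks with acetylation and without CTCF had Etfbkmt, Cpsf6, a gene of RNA 3' end processing, Igsf3 and Tmem68 as the nearest protein-coding gene, with folds of 17.7, 17.7, 15.3 and 14.5. Their summits lay 10.2, 75.4, 35.7 and 146 kb from the gene end, that of Igsf3 inside the gene. H3K27ac peaks with Trim33 had a median fold of 10.6, against 6.67 without it (log2 difference 0.58 ± 0.02, SE; adjusted permutation p = 1.67e-05). Trim33 peaks with H3K27ac were slightly lower than those without, with median folds of 5.63 and 5.70 (log2 difference -0.04 ± 0.01, SE; adjusted permutation p = 0.00145), a difference not past the threshold away from gene ends (adjusted permutation p = 0.823) or by −log10 q (adjusted permutation p = 0.117). The share of H3K27ac peaks with Trim33 rose from 1.70% in the lowest decile of height to 18.4% in the highest. Local placement by 20 to 200 kb gave 128 ± 10.9 overlaps, an excess of 14.7 times.

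**Figure D2:**
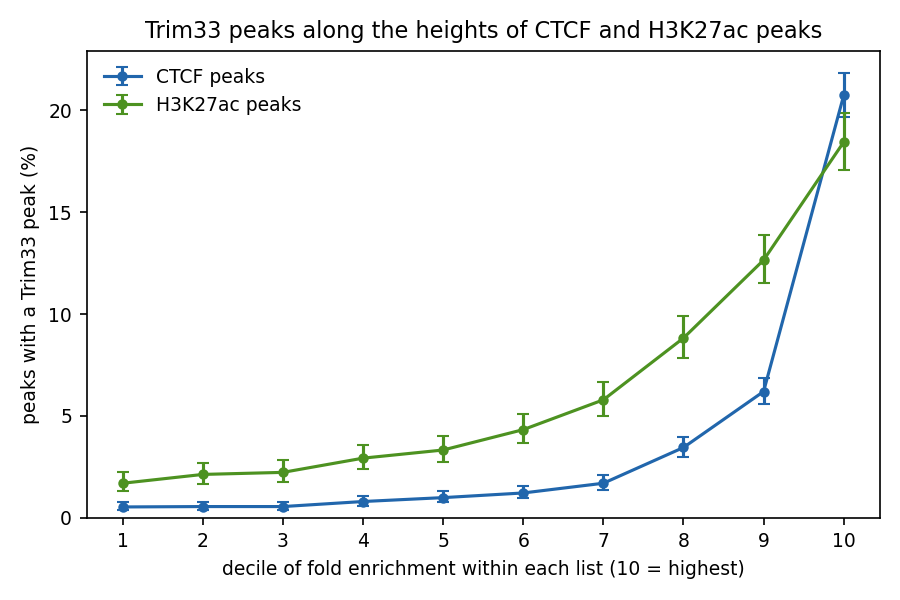
Each point is the share (%) of CTCF or H3K27ac peaks that overlap a Trim33 peak, by decile of the authors' fold within that list, with 95% Wilson intervals. The share rises to 20.7% of the highest CTCF decile and 18.4% of the highest H3K27ac decile.

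A smaller share of CTCF peaks overlapped acetylated sites. Of the CTCF peaks, 4315 (8.23%, 8.00 to 8.47) overlapped an H3K27ac peak, where random placement gave 759 ± 27.5, an excess of 5.69 times (one-sided permutation p = 0.001, the smallest possible). Of the H3K27ac peaks, 14.6% overlapped CTCF and 6.23% overlapped Trim33. Dnajc11, Med4 and Dhx8 were near such sites, with H3K27ac folds of 21.5, 10.3 and 11.8, while the CTCF peaks near Glrx3 and Csrp1 had no H3K27ac peak. H3K27ac peaks with CTCF had a median fold of 8.73 against 6.55 (log2 difference 0.37 ± 0.01, SE; adjusted permutation p = 1.67e-05). Local placement gave 1695 ± 39.2 overlaps, an excess of 2.55 times. All 3 lists were called against the same input library, so part of any overlap may come from that shared control.

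Trim33 peaks fell into 4 classes of similar height. There were 1422 with CTCF alone (32.1%), 1328 with H3K27ac alone (30.0%), 557 with both (12.6%) and 1119 with neither (25.3%). Median folds were 5.92, 5.63, 5.67 and 5.63. Near a gene end lay 66.4% of the peaks with both, 52.6% of those with H3K27ac alone, 24.3% of those with CTCF alone and 21.5% of those with neither. Of the peaks with both marks, the highest was that on chromosome 17 with a fold of 20.4. Next came one 6.41 kb from Slc38a3, an amino acid transporter gene, with 16.9. Those that followed lay 0.763 kb from an end of Mycn (gene ID 18109), a proto-oncogene of the Myc family, with 13.7, and 11.4 kb from Foxj1, a regulator of motile cilia, with 12.9. Further ones were near Cyria, Cdk9, the kinase of transcription elongation, Laptm4a, Crabp2, a retinoic acid binding protein gene, and Ephb3, an ephrin receptor gene, with folds of 12.5, 11.8, 11.3, 11.2 and 10.9, and inside Col18a1, a basement membrane collagen gene, with 10.7. The highest peaks with neither mark lay inside Gse1 with a fold of 20.0, with Gins2 the nearest protein-coding gene by its end, inside Ust, a sulfotransferase gene, with 16.9, inside Tmem260 with 16.1, near Ermard with 15.5 and inside Tet3, which encodes an enzyme that oxidises methylated cytosine, with 14.4.

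Within H3K27ac peaks, Trim33 was more frequent where CTCF was present. It overlapped 662 of the 4395 H3K27ac peaks with CTCF (15.1%, 14.0 to 16.2) and 1211 of the 25652 without (4.72%, 4.47 to 4.99). The odds ratio was 3.58 (95% interval 3.23 to 3.96; Fisher's exact p = 3.54e-119, two-sided). Within strata formed by quintiles of H3K27ac width and of height it was 2.37 (2.14 to 2.63, Mantel-Haenszel). Peaks within a stratum still differ in both. Among Trim33 peaks alone the relation had the other sign, as those with CTCF overlapped H3K27ac less often (odds ratio 0.33, 0.29 to 0.38; Fisher's exact p = 1.41e-69, two-sided). The latter odds ratio is taken over sites that were selected for having Trim33, and neighbouring peaks are not independent, so both p-values are too small.

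The fourth question was which genes had Trim33 at their ends. Of 21887 protein-coding genes, 1458 (6.66%) had a Trim33 summit within 1 kb of an end, and 1142 of them (78.3%) also had an H3K27ac summit there. Among all 21887 genes, 8574 (39.2%) had an H3K27ac summit within 1 kb of an end. Of 15 gene lists fixed before the data were examined, 3 had Trim33 more often than other genes, namely ribosomal protein genes, imprinted genes and genes of chromatin architecture. Trim33 stood at 24 of 101 genes of the ribosomal list (23.8%; odds ratio 4.42, 2.67 to 7.10; Fisher's exact adjusted p = 5.2e-07 by Benjamini-Hochberg over the 15 lists). Among them were Rpl4, Rpl8, Rps3 and Rps19, and also Rps6ka1, a kinase gene that shares the prefix. With ribosomal proteins alone, a choice made after seeing the data, it stood at 21 of 87 (odds ratio 4.51, Fisher's exact adjusted p = 2.77e-06). The chromatin list had 6 of 26 genes with Trim33 (odds ratio 4.22, 1.38 to 10.9; Fisher's exact adjusted p = 0.0313). Its members were Trim33 itself (gene ID 94093, chromosome 3) with a fold of 6.83, Eed and Suz12, both of the Polycomb repressive complex, with 6.67 and 5.33, Smc3, a cohesin subunit gene, with 6.03, Hdac1, a histone deacetylase gene, with 5.22, and Ctcf (gene ID 13018, chromosome 8) with 4.93. All 6 of these Trim33 peaks overlapped H3K27ac, with folds from 11.7 at Hdac1 to 22 at Trim33. Under a stricter list of Trim33 peaks (−log10 q of at least 10, 637 peaks), no list passed the test, and among genes with H3K27ac at an end only the ribosomal list did (odds ratio 2.99, Fisher's exact adjusted p = 0.000678). That background matched genes for the presence of H3K27ac but not for its height. Trim33 was more frequent at higher H3K27ac peaks, so height may contribute to this call, which was not tested.

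Imprinted genes had Trim33 at 10 of 34 members (29.4%; odds ratio 5.87, 2.50 to 12.8; Fisher's exact adjusted p = 0.000376). These were Cdkn1c, a cell cycle inhibitor gene, Dio3, a thyroid hormone deiodinase gene, Gnas, Kcnq1ot1, a long noncoding RNA, Nnat, Peg3, Plagl1, Usp29, and the neighbours Peg10 and Sgce. The 10 genes had 8 peaks, since Peg10 with Sgce and Peg3 with Usp29 each shared 1 peak. Of the 8 peaks, 6 overlapped neither CTCF nor H3K27ac, 1 overlapped H3K27ac and 1 both. Folds ran from 3.40 at the peak shared by Peg3 and Usp29, with its summit inside Peg3, to 6.83 at Kcnq1ot1. Among genes with H3K27ac at an end, 5 of 15 imprinted genes had Trim33, not past the threshold (odds ratio 3.26; Fisher's exact adjusted p = 0.133). The H19 and Igf2 region, whose imprinting control region is a known CTCF site, had its Trim33 peaks outside that 1 kb limit. There, on chromosome 7 from 142579934 to 142580920, a Trim33 peak of fold 10.9 lay 2117 bp from the end of H19 and overlapped a CTCF peak of fold 35.5. A weaker one of fold 3.17 stood at a CTCF peak of fold 21.3, and neither overlapped H3K27ac. Counting any Trim33 peak inside an imprinted gene or within 5 kb of it, 18 of the 34 genes had one. Among these were Grb10, a growth factor receptor adaptor gene, with a fold of 11 at a CTCF peak of fold 34.1, and Mest with 6.89 at a CTCF peak of fold 38 and an H3K27ac peak of fold 8.89.

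**Figure D3:**
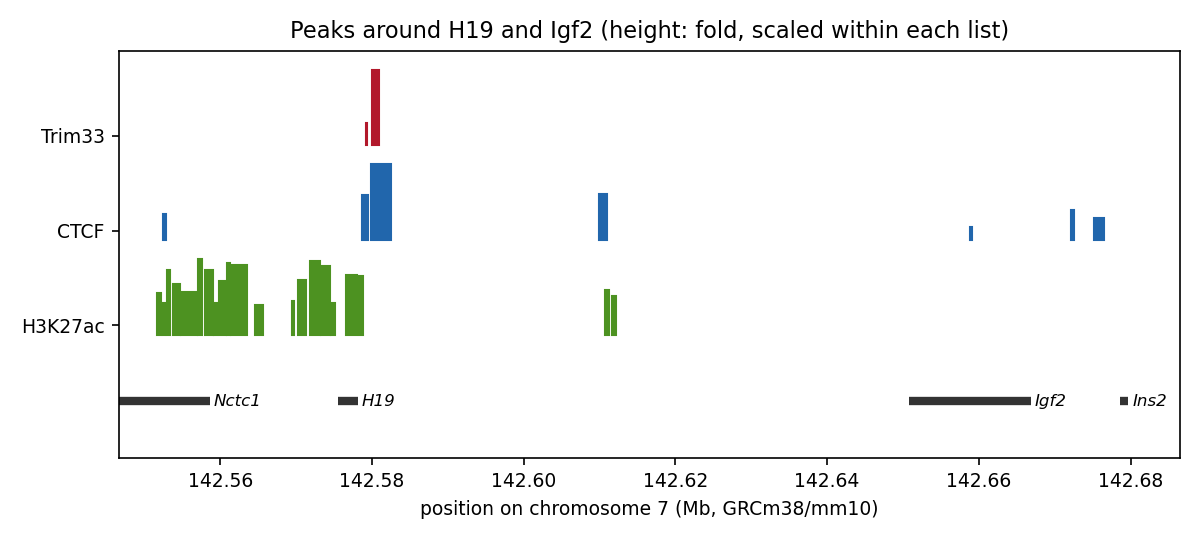
Peaks of the 3 lists around H19 and Igf2 on chromosome 7 (Mb, GRCm38), drawn to scale along the chromosome with a minimum drawn width, heights giving fold scaled to the highest peak shown of each list. Both Trim33 peaks, of folds 3.17 and 10.9, lie upon CTCF peaks beside H19, and neither overlaps an H3K27ac peak.

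Signalling and germ layer genes carried Trim33 peaks of modest height, and none of those lists passed the adjusted test. Of 34 Nodal and TGF-beta genes, 5 had Trim33 (odds ratio 2.42, 0.73 to 6.34; Fisher's exact adjusted p = 0.218). They were Smad7, an inhibitor of the pathway, with a fold of 6.83, Trim33, Smurf1, a ubiquitin ligase gene, with 6.00, Acvr2a, an activin receptor gene, with 5.63, and Smad4, the shared mediator, with 4.82. Of 24 primitive streak genes, 5 had Trim33 (odds ratio 3.70, 1.08 to 10.3; Fisher's exact p = 0.0191, adjusted p = 0.0717). These were Sp5, a Wnt target, with a fold of 6.83, Evx1 and Foxa2 with 5 each, Fgf8 with 4.67 and Dll1, a Notch ligand gene, with 4.62. With Trim33 peaks held to a −log10 p of at least 7, a setting chosen after seeing the data, this list was past the threshold (odds ratio 4.24; Fisher's exact adjusted p = 0.0493). The BMP list had Bambi with 6.33, Id2 with 4.93 and Bmp7 with 4.25 (Fisher's exact adjusted p = 0.333), and the Wnt list had Sp5, Tcf7l1 with 6.00 and Fzd8 with 4.61 (adjusted p = 0.310). The neural list had Irx3 with 5.99, Sox2 with 5.51 and Sox1 with 4.82 (Fisher's exact adjusted p = 0.373). Sox2, Tbx3 with 5 and Lin28a with 4.94 were the pluripotency members (Fisher's exact adjusted p = 0.373). The cardiac list had Hand1 with 5.59 and Nkx2-5 with 5, the endoderm list Apoa1 with 5.25 and Foxa2, and the blood and endothelium list Fli1 with 6.83 and Kit with 3.75. The lowest adjusted p of those 3 lists was 0.74 (Fisher's exact test). No Hox gene of 39 had Trim33 within 1 kb (Fisher's exact adjusted p = 0.276), and the zinc finger (Zfp) genes had it at 30 of 400 (adjusted p = 0.652). With a window of 5 kb, 9 lists passed the adjusted test. They included the Wnt (9 of 20 genes, odds ratio 6.71), BMP (9 of 22, 5.68), primitive streak (9 of 24, 4.92) and pluripotency lists (9 of 25, 4.61). The Nodal list (12 of 34, 4.475) and the neural list (8 of 26, 3.64) passed too. Fisher's exact adjusted p was 0.000564 for the Nodal and Wnt lists, 0.00152 for the primitive streak list and 0.00845 for the neural list. The others were the imprinted, ribosomal and chromatin lists.

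**Figure D4:**
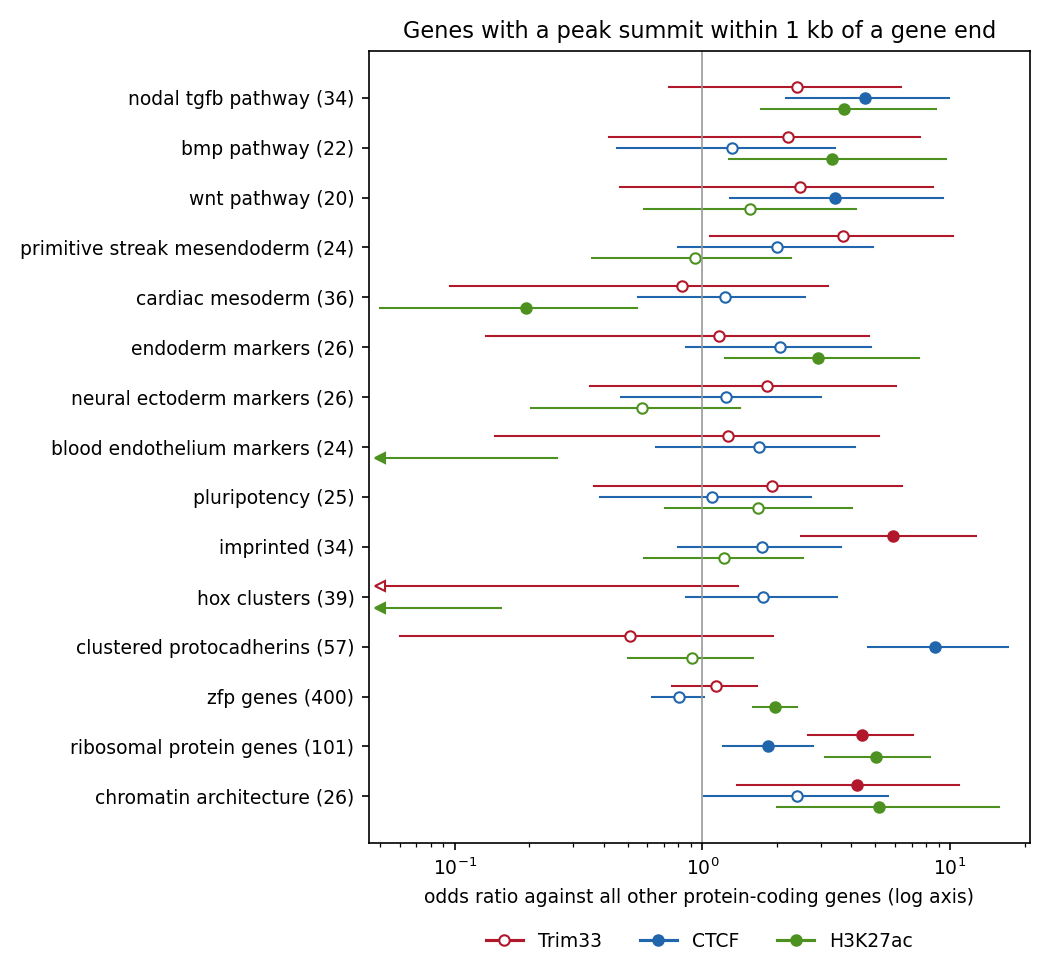
Odds ratios (log axis) of a peak summit within 1 kb of a gene end for the members of each list against all other protein-coding genes, with 95% intervals, for the 3 antibodies; filled marks have an adjusted p under 0.05, arrows stand for an odds ratio of 0 and list sizes are in brackets. The imprinted list stands at 5.87 for Trim33 and the clustered protocadherins at 8.69 for CTCF.

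The same lists were tested for CTCF and H3K27ac, and the ribosomal list was past the threshold for all 3 antibodies. No library with an unspecific antibody was analysed here, so sites that enrich with any antibody stay open for the ribosomal list. CTCF stood at 43 of 57 clustered protocadherin genes, which encode cell surface proteins of neurons (75.4%; odds ratio 8.69, 4.66 to 17.2; Fisher's exact adjusted p = 1.76e-13), and Trim33 at Pcdhga11 and Pcdhgc4 among them (Fisher's exact adjusted p = 0.736). Over whole genes in strata of length, a setting chosen after seeing the data, Trim33 stood at 21 of the 57 (odds ratio 3.42, 1.91 to 6.11), which rests on 3 peaks in the Pcdhg cluster, whose genes overlap one another. Many of these genes share ends and peaks, so they are not independent. With genes whose ends lie within 2 kb of each other counted as 1 unit, a choice made after seeing the data, CTCF stood at 9 of 18 such units, not past the threshold (odds ratio 2.68, 0.94 to 7.64; Fisher's exact adjusted p = 0.146). CTCF was also more frequent at Nodal and TGF-beta genes (21 of 34; odds ratio 4.55, Fisher's exact adjusted p = 0.000104), Wnt genes (11 of 20; odds ratio 3.44, adjusted p = 0.0306) and the ribosomal list (40 of 101; odds ratio 1.85, adjusted p = 0.0156). Among genes with H3K27ac at an end, 1 list, the protocadherins counted gene by gene, was past the threshold for CTCF. The Wnt call was also lost with −log10 q of at least 10 (Fisher's exact adjusted p = 0.247), and that of the ribosomal list by nearest gene (adjusted p = 0.459). H3K27ac stood at 24 of 34 Nodal and TGF-beta genes (odds ratio 3.73, Fisher's exact adjusted p = 0.000719), among them Nodal, Tdgf1, its co-receptor, and Foxh1. It also stood at 15 of 22 BMP genes (odds ratio 3.33), at 17 of 26 endoderm genes, such as Sox17 and Gata6 (odds ratio 2.94; Fisher's exact adjusted p = 0.0136 for both lists). The BMP call was lost within 5 kb (Fisher's exact adjusted p = 0.089) and with −log10 q of at least 10 (adjusted p = 0.0769). H3K27ac stood at 20 of 26 chromatin genes (odds ratio 5.19, Fisher's exact adjusted p = 0.000434), at 77 of 101 genes of the ribosomal list (odds ratio 5.02, adjusted p = 7.24e-13) and at 222 of 400 Zfp genes (odds ratio 1.96, adjusted p = 2.62e-10). It was rarer at cardiac genes, with 4 of 36, namely Fgf10, Gata4, Gata6 and Myh7 (odds ratio 0.194, Fisher's exact adjusted p = 0.000927). None of the 24 blood and endothelium genes (Fisher's exact adjusted p = 2.97e-05) and none of the 39 Hox genes (adjusted p = 2.23e-08) had an H3K27ac summit within 1 kb. The Hox genes lie together in the Hoxa, Hoxb, Hoxc and Hoxd clusters, so they are not independent and their p-value is too small. By nearest gene the blood and endothelium call was lost (Fisher's exact adjusted p = 0.0536). Imprinted genes had H3K27ac at 15 of 34 members and CTCF at 13 of 34, neither past the threshold (Fisher's exact adjusted p = 0.692 and 0.18).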

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

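The excess of overlap between the 3 lists kept its direction and passed the test in every alternative run, from 11.5 to 64.6 times for Trim33 at CTCF, 14.7 to 42.8 times for Trim33 at H3K27ac and 2.55 to 6.81 times for CTCF at H3K27ac. Both odds ratios between CTCF, Trim33 and H3K27ac likewise kept direction and call. Over all results and settings, 179 of 247 values kept their direction and side of the threshold, or for shares stayed inside their interval, or for counts of lists stayed within 1.5 times the main count. That count is inflated, because the setting with ribosomal proteins alone changes only the ribosomal list. Its values for the other lists repeat the main ones and were counted as kept. The height of Trim33 peaks with H3K27ac, lower by a log2 difference of -0.04, lost its call with −log10 q in place of fold (a difference of -0.207) and away from gene ends (-0.00328), as did that with CTCF away from gene ends (0.0266); the cause was not tested. The share of peaks at gene ends depends by construction on the window: within 5 kb it was 61.7% for Trim33, 46.7% for CTCF and 62.7% for H3K27ac, and with protein-coding genes only 30.1%, 12.9% and 34.2%. The number of gene lists past the adjusted threshold was 3 for Trim33, 9 within 5 kb, 10 by nearest gene, 9 over whole genes in strata of length (chosen after seeing the data), 1 among acetylated genes and 0 at −log10 q of at least 10. In that last setting 168 background genes had a peak and the test could exclude little: the imprinted, chromatin, Nodal, BMP, Wnt, streak, endoderm, neural, blood and pluripotency lists turned to an odds ratio of 0, and the Zfp list to 0.977. Other Trim33 odds ratios that changed side of 1 were those of the cardiac list (2.34 within 5 kb, 3.36 by nearest gene with a call gained, 1.56 over whole genes), the Zfp list (0.932, 0.885 and 0.978 in the same order, 0.747 among acetylated genes), the Hox list (1.20 within 5 kb), the endoderm list (0.406 among acetylated genes), the blood list (0.698 at −log10 p of at least 7, chosen after seeing the data) and the protocadherins (3.42 over whole genes, with a call gained through 3 peaks); the cause was not tested otherwise. The CTCF odds ratio of the protocadherins among acetylated genes has no finite value, as every such gene had CTCF. For CTCF the number of lists was 4, against 7 within 5 kb and 1 among acetylated genes. With neighbouring genes as 1 unit, chosen after seeing the data, it was 3 for CTCF and the protocadherins lost their call (odds ratio 2.68), where their 57 genes form 18 units. The analyses of motifs and of repeats at summits, and their alternatives, were not run. No paired analysis was possible because each antibody has 1 library.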

Other observations

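H3K27ac peaks within 1 kb of each other were joined into 16836 regions. The longest covered 42.9 kb at Trim71, a regulator of early developmental timing, and held 1 Trim33 peak and 5 CTCF peaks. Next came Myh9, a nonmuscle myosin gene, with 30.7 kb, Unc5b, a netrin receptor gene, with 26.3 kb, Ank2, an ankyrin gene, with 24.6 kb, and Actn4, an actinin gene, with 23.5 kb. Pmepa1, a TGF-beta target and feedback inhibitor, had 22.6 kb with no Trim33 peak and 1 CTCF peak. In the Hox clusters no H3K27ac peak was found, and CTCF had 12 peaks over the Hoxa cluster, 19 over Hoxb, 7 over Hoxc and 12 over Hoxd. Trim33 had no peak in the Hoxa cluster, 1 of fold 6.08 in Hoxb, 2 in Hoxc with a highest fold of 6.83, and 1 of fold 12.9 in Hoxd. These regions were chosen after their values were seen.

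The tests below were chosen after the patterns had been seen, apart from that with −log10 q of at least 10, which was fixed before, and the rules for reading both carry-over tests were changed after their values were known. Trim33 peaks met CTCF peaks far more often than placement gives. Acetylated chromatin and gene ends do not account for it alone, because Trim33 peaks over 5 kb from gene ends and outside joined H3K27ac regions met CTCF in 602 of 1206 cases, 16.6 times the local placement. Carry-over of reads from the CTCF library stays open, since 43.7% (38.4 to 49.1) of the strongest CTCF peaks without H3K27ac had Trim33, a share that counting noise at a single rate near the calling limit can also give, and the ratio of Trim33 to CTCF enrichment in those had quartiles of 0.116 and 0.172. At weaker CTCF sites the median ratio was 5.25 times that at the strongest, where the lowest called Trim33 fold allows 1.23 or more. This decides nothing, because called Trim33 peaks had similar median folds at the weaker and the strongest sites (5.63 and 6.83). CTCF fold differed by the choice of sites, at 3.59 to 9.33 and 37.4 to 57.7. The ratio was also taken only over the 64 of 24334 weaker peaks (0.263%) where Trim33 was called, so carry-over at the others is not measured. Sites that enrich with any antibody stay open, since CTCF peaks with Trim33 also had H3K27ac more often within deciles of CTCF height (odds ratio 3.90, 3.50 to 4.35) and no library with an unspecific antibody was analysed here, so a shared property of these sites and binding of Trim33 there cannot be told apart.

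The X chromosome held 17 Trim33 peaks, or 0.0994 per Mb against 1.79 per Mb on autosomes, a ratio of 0.0556, where CTCF had a ratio of 0.230 and H3K27ac 0.286. Fewer sites on the X do not account for all of it, since X peaks carried Trim33 less often than autosomal peaks of like height (odds ratio 0.497, 0.259 to 0.955, at CTCF peaks and 0.152, 0.0719 to 0.321, at H3K27ac peaks). A single X copy in a shallow library was modelled by thinning the tags recovered from the authors' fold and p (within 0.001 of −log10 p for 100% of Trim33 peaks), which kept 43.1% of autosomal Trim33 peaks. With the X site density of CTCF or H3K27ac this predicts 44.8 or 66.0 Trim33 peaks, above the 9.90 to 27.2 that 17 counts allow (95% Poisson interval), yet it stays open as it rests on a model of equal halving. The background recovered was at its genome-wide minimum for 88.2% of X peaks and 27.1% of autosomal ones, while the Y chromosome held 8 Trim33, 14 CTCF and 0 H3K27ac peaks, all from 90738684 to 90811330 around the edge of the region it shares with X, which leaves the number of X copies open; the labels do not give the sex of the cells, and no biological explanation was tested.

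Imprinted genes had Trim33 at 10 of 34 members, mostly in weak peaks. Neighbours that share a peak do not account for it, as the odds ratio was 4.37 (1.69 to 10.1) with neighbours counted as 1 unit. CTCF or H3K27ac at the same gene ends does not either, with an odds ratio of 4.97 (2.31 to 10.7) within strata of both. With −log10 p of at least 7 for Trim33 it was 3.45 (1.17 to 8.51, with 6 of 34 genes), lower than the 5.87 of the full list. Peg10 and Sgce among these 6 share 1 peak, and neighbours were not joined in this setting. No member had a summit of −log10 q of at least 10 within 1 kb of an end. Sites that enrich with any antibody stay open, as no library with an unspecific antibody was analysed here. Of the 8 peaks, 6 overlapped neither CTCF nor H3K27ac. Those libraries carry another project code and their lists another cut-off, so absence there decides nothing. Trim33 peaks of −log10 p of at least 7 with neither gave an odds ratio of 23.4 (6.97 to 62.1, with 5 of 34 genes). That test was chosen after the pattern had been seen, and Peg10 and Sgce among the 5 genes share 1 peak. Of the 23 peaks inside imprinted genes or within 5 kb of them, 7 overlapped neither. The CpG content of these promoters and biological explanations were not tested.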
